A study of Homo sapiens with 12 samples.

How the data were processed

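RNA from 12 samples of Huh-7 cells, 4 per group, was measured on Affymetrix HG-U133 Plus 2.0 arrays, 1 array per sample, from 150 ng of total RNA. The groups were taken from the labels: transfection reagent without oligonucleotide (control), gap-A13 and gap-P13, each oligonucleotide at 20 nM for 24 h. The deposited values are signal intensities on a linear scale, 1 per probe set and array, and the submitters' processing notes name MAS5, whose version is not given in the sources used here. The values ran from 0.0702 to 55596, and their mean between the 2nd and the 98th percentile was the same on all 12 arrays, as MAS5 global scaling leaves it. No detection calls were used. The arrays were not normalized further.

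Of 54675 probe sets, 62 are array controls, 41091 name 1 gene, 1801 name several and 11721 list none. The symbols number 19775, of which 19735 were matched by gene ID to the RefSeq table of the GRCh38 assembly. That table served for gene body lengths and to mark lncRNA genes. Signals below the 25th percentile of all values (18.6) were raised to it, and values were taken to log2. Probe sets with a mean below the 40th percentile (37.9) were left out, and each gene was represented by its probe set with the highest mean over all 12 arrays, which left 14078 genes, 14064 of them with a length. Probe sets without 1 gene symbol were left out of the gene tests and tested separately.

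One linear model over all 12 arrays was fitted with limma 3.58.1 in R 4.3.3, with moderated variances that follow the intensity trend. The 3 comparisons were gap-A13 against control, gap-P13 against control and gap-A13 against gap-P13. Genes were called at an adjusted p (Benjamini-Hochberg, two-sided) under 0.05 within each comparison. Errors of log2 fold changes are standard errors of this model, and those of signals are SD. Data were simulated with the same number of arrays and genes, with 13878 of the 14078 genes left unchanged in each comparison. The fit recovered 45.8%, 55.4% and 42.9% of genes given a log2 change of 0.5 in the 3 comparisons. It recovered 78.7%, 76.4% and 69.0% at a change of 1 and 92.4%, 95.8% and 92.4% at a change of 2, and called 0.0288% of unchanged genes. The real comparisons called a far larger share of genes, on which the adjusted p depends, so these rates are not those of the real fits. Array measures were compared between groups by exact permutation of the group labels (two-sided).

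Gene lists, comparisons, alternatives and the rule for named genes were set before the data were examined. The 26 lists, holding 546 genes, covered stress and inflammatory responses, liver function, lipid synthesis, drug metabolism, cell cycle, ribosomal proteins, RNA decay, phosphorothioate-binding proteins, autophagy, extracellular matrix and 4 sets of markers of other cell types. Each was tested with camera of limma at its preset inter-gene correlation of 0.01, and the 78 p-values were adjusted together. Camera with an estimated correlation and fry were alternatives. The rule named the 10 largest rises and the 10 largest falls against control (5 in the direct comparison) among called genes whose groups did not overlap, the 5 largest changes shared in each direction, the 4 members of each list with the smallest p in each comparison, and APOB, RNASEH1, GAPDH and ACTB. Not every gene that the rule gives is described. Overlap of the 2 comparisons with control was set against 100 simulated pairs of unchanged groups that shared controls, and against the 6 splits of the controls into 2 and 2. The relation to gene length was the Spearman rank correlation across genes, and camera on the longest 10%, its 3 p-values adjusted together.

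Alternatives were quantile normalization, median centring, no floor, a pseudocount of 16, no filter or one at the 60th percentile, the mean of a gene's probe sets, all probe sets singly, 3 other variance models, a fit to the 8 arrays compared, the replicate number as a block and leaving out each array. Quantile normalization, spike scaling, no floor and the pseudocount chose the probe set of a gene anew. Scaling on the hybridization spikes and list tests on log2 fold changes less the median of each gene's length decile were added after the data had been seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. The oligonucleotide sequences were not used here, so matches between them and transcripts were not analysed here.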

Results

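Transcript levels were measured in Huh-7 cells, an established human hepatoma line, on 12 whole-genome expression arrays, 1 per sample. The samples formed 3 groups of 4. Control cells received the transfection reagent Lipofectamine without oligonucleotide. The other groups were transfected for 24 h with 20 nM of gap-A13 or of gap-P13. Both are LNA-gapmer antisense oligonucleotides, a class that pairs with RNA and recruits RNase H1 to cut it. The series title asks about off-target effects of such oligonucleotides in human cells, so each comparison with control asks which transcripts an oligonucleotide changed, and the direct comparison asks where the 2 oligonucleotides differed. The sequences and intended targets of the oligonucleotides were not used here. Values were MAS5 signal intensities, and 14078 genes were tested. Arrays of a group correlated with r of 0.979 to 0.983 across genes, which are not independent replicates. The first principal component held 42.5% of the variance and set the gap-P13 arrays apart from the rest, and the second held 12.5% and set gap-A13 apart from control. Having 4 arrays per group limits the precision, and the median standard error of a log2 fold change was 0.11. Nothing beyond the labels says that the samples of a group were separate cultures, so the p-values measure the spread between these samples.

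APOB, which encodes the structural protein of very low and low density lipoproteins, fell steeply with gap-A13, from an intensity of 19861 ± 649 in control to 2415 ± 145 (SD, n = 4 each), a log2 fold change of -3.04 ± 0.05 (SE). KMT2E, a chromatin regulator, had the largest fall, from 1561 ± 180.1 to 134.7 ± 21.9 (SD, n = 4), and FNBP1L, which links membrane curvature to actin assembly, fell by 3.17 on the log2 scale. Losses were larger than gains, with 219 genes lower and 43 higher at least 2-fold (198 and 24 with a pseudocount added before logs), and 30 lower and 2 higher at least 4-fold. In all, limma called 2629 of 14078 genes at adjusted p under 0.05, 1402 higher and 1227 lower. The 4 treated and 4 control values did not overlap for 3296 genes (23.4%), where chance gives 2.86%.

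The 10 largest falls with gap-A13 by the rule for named genes were KMT2E, TMEM117, GPHN, FNBP1L, PTPRG, SOX6, APOB, MCU, PSD3 and TBCK, with log2 fold changes of -3.54 to -2.60. For every gene named here as fallen or risen, all 4 treated arrays lay beyond all 4 control arrays. The call for KMT2E had an adjusted p of 2.95e-12 and that for APOB 1.17e-15. A further APOB probe set gave -3.42. MCU, the pore of the mitochondrial calcium uniporter, fell by 2.79, SOX6, a transcription factor, fell by 3.13, and PTPRG, a receptor tyrosine phosphatase, fell by 3.16. The 4 other SOX6 probe sets gave log2 fold changes of -2.81 to 0.17. GPHN encodes the scaffold protein gephyrin. Its value of -3.27 has 2 treated arrays at the floor of the signal scale, which sets its size, and its 2 other probe sets gave -1.98 and -0.82. The last of these represented GPHN when the floor was dropped, and then missed the threshold (adjusted p = 0.0658). Of the largest rises, TEX19 went from 145.1 ± 19.99 to 475.1 ± 85.3 (SD, n = 4), a log2 fold change of 1.71 with an adjusted p of 1.58e-06. RGCC, a regulator of the cell cycle, rose by 1.54, and KIF7, a kinesin of the primary cilium, by 2.04. LY96, the co-receptor of Toll-like receptor 4, rose by 1.33 from an intensity of 27.3. DNAJC12 rose by 1.49 with 2 control arrays at the floor, and PRODHLP went from 14.8 to 85.0 with 3 control arrays at the floor. TCP10L rose by 1.52, though its mean over 2 probe sets was 0.87 with an adjusted p of 0.056. The remaining members of the largest 10 were GTF2IP20, PDGFRA and AURKC, whose adjusted p values of 0.0162, 0.0202 and 0.0202 depended on single arrays. GTF2IP20 gave 0.0528 without control replicate 1. PDGFRA gave 0.0528 without control replicate 2, 0.0533 without gap-A13 replicate 2 and 0.062 without gap-A13 replicate 3. AURKC gave 0.0566 and 0.0577 without control replicates 2 and 3, and 0.053 and 0.0605 without gap-A13 replicates 1 and 4.

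**Figure D1:**
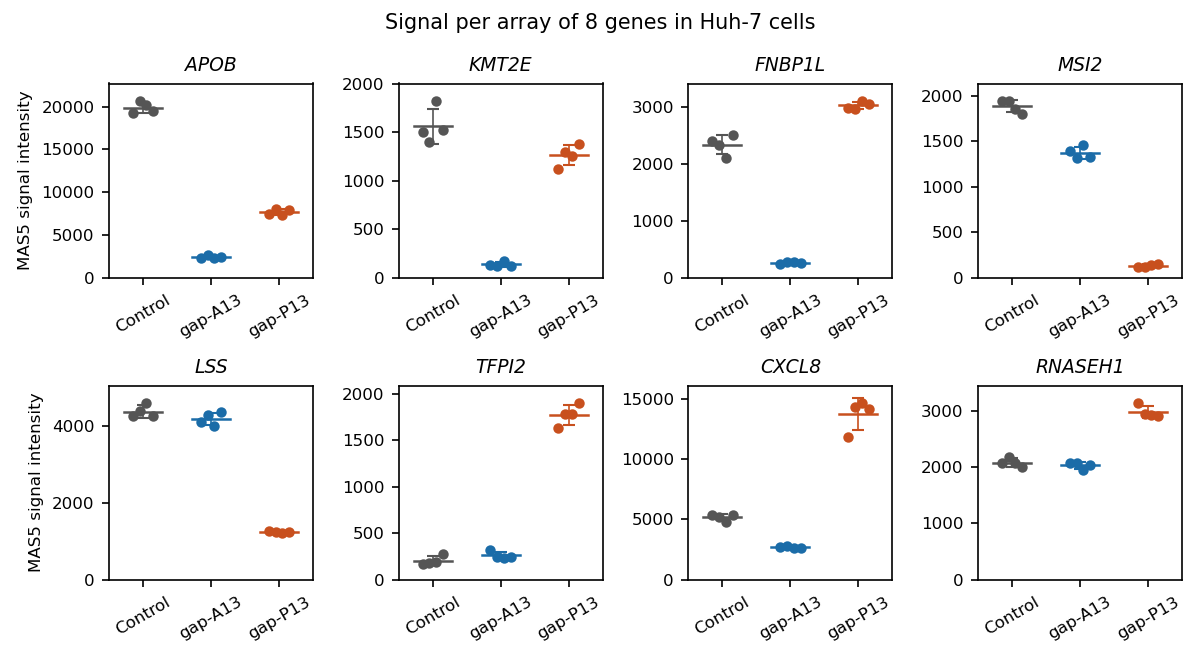
MAS5 signal intensity of 8 genes on each of the 12 arrays (4 control, 4 gap-A13, 4 gap-P13). Points are arrays, horizontal lines group means and bars SD. APOB averaged 19861 in control, 2415 with gap-A13 and 7651 with gap-P13.

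Among 26 gene lists fixed beforehand, 4 were called with gap-A13 by camera, which compares the members of a list with all other genes. Extracellular matrix and TGF-beta genes were lower, with 8 of 19 measured members fallen and 1 risen (median log2 fold change -0.13, adjusted p = 0.000164). TGFB2, the transforming growth factor beta 2 ligand, fell by 2.24, the integrin subunit ITGAV by 0.70, the TGF-beta binding protein LTBP1 by 0.69 and the actin-binding protein TAGLN by 0.49. Heat shock genes were higher, with 7 of 13 risen and 0 fallen (median 0.16, adjusted p = 0.00424), among them the collagen chaperone SERPINH1 at 0.45, the co-chaperones DNAJB1 at 0.27 and DNAJA1 at 0.22, and BAG3 at 0.34. Immediate early genes were lower, with 6 of 19 fallen and 0 risen (median -0.04, adjusted p = 0.0154, adjusted p = 0.1 with an estimated correlation). CCN1 fell by 0.73, CCN2 by 0.48 and the phosphatase DUSP1 by 0.21. NF-kappaB and inflammatory genes were lower by a small margin, with 4 of 19 fallen and 1 risen (median -0.08, adjusted p = 0.0414, adjusted p = 0.113 with an estimated correlation). The chemokine CXCL8 fell by 0.94 and NFKB1, which encodes an NF-kappaB subunit, by 0.96. NFKBIZ, a nuclear regulator of NF-kappaB, rose by 0.43, though its mean over all probe sets gave 0.19 with an adjusted p of 0.146. The call for this list ended without control replicate 1 (adjusted p = 0.0761), gap-A13 replicate 1 (adjusted p = 0.0511) or gap-A13 replicate 3 (adjusted p = 0.0707), and under quantile normalization (adjusted p = 0.0588). Adjusted over the list alone, the fallen members were 6 in the NF-kappaB list, 6 among immediate early genes, 8 in the matrix list and 1 among heat shock genes, where 7 rose. In all 4 lists the members' mean, relative to that of all genes, moved in the called direction on all 4 treated arrays. Many lists without a call, p53 targets and cell cycle genes among them, also moved 1 way on all 4 arrays. This does not set called lists apart.

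With gap-P13, cholesterol and fatty acid synthesis genes fell together while inflammatory and immediate early genes rose. LSS, the lanosterol synthase of cholesterol synthesis, fell from 4387 to 1246, a log2 fold change of -1.82 ± 0.05 (SE, n = 4 each), and CXCL8 rose from 5165 to 13761, a log2 fold change of 1.41 ± 0.06. MSI2, an RNA-binding protein gene, had the largest fall, from 1882 ± 67.1 to 129.9 ± 15.6 (SD, n = 4). APOB fell to 7651 ± 344.5 (SD, n = 4), a log2 fold change of -1.38 ± 0.05, and RNASEH1, which encodes the enzyme that gapmers recruit, rose by 0.52 ± 0.05. In all, limma called 7070 of 14078 genes, 3884 higher and 3186 lower, with 437 higher and 905 lower at least 2-fold (286 and 1146 on the hybridization spikes, 326 and 802 with a pseudocount), and 46 higher and 148 lower at least 4-fold. Values of the groups did not overlap for 6404 genes (45.5%), where chance gives 2.86%.

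The largest rises with gap-P13 by the rule for named genes had log2 fold changes of 3.78 to 2.56. TFPI2, a serine protease inhibitor, rose from 204.0 ± 51.6 to 1775 ± 109.3 (SD, n = 4), a log2 fold change of 3.15 with an adjusted p of 4.73e-11. EMP1 rose by 3.03, GEM by 2.56, and BCL2A1, an inhibitor of apoptosis, by 2.89 with 1 control array at the floor. ZCCHC12 rose by 2.75, RAB39B by 2.85 with 1 control array at the floor and SLAMF7 by 2.80 with 2. MIR181A2HG, a microRNA host gene, rose by 3.78, and SUCLA2-AS1 went from 15.3 to 157.5, each against controls of which 3 were at the floor. The largest falls were MSI2 (-3.86, adjusted p = 1.5e-14), TEX15, ZDHHC14, SNX19, PTPRG, SHANK2, CAMK2D, IMMP2L, MICAL3 and UBASH3B, down to -2.95. The kinase gene CAMK2D fell by 3.08 and the synaptic scaffold gene SHANK2 by 3.13. SNX19 had 3 treated arrays at the floor and IMMP2L 1. The 2 other ZDHHC14 probe sets gave -0.85 and -0.77, against -3.34, the 2 other SNX19 probe sets -2.77 and -0.60, and the 3 others of MICAL3 -2.78 to -0.33. The 8 other MSI2 probe sets gave log2 fold changes of -3.67 to 0.77, and 1 of them was called in the opposite direction. All 4 treated arrays lay beyond all 4 control arrays for every gene named in this and the preceding account of gap-P13. APOB had an adjusted p of 2.89e-12 and RNASEH1 1.52e-07. The 2 other RNASEH1 probe sets gave 0.55 and 0.19, the latter not called (adjusted p = 0.209). With gap-A13, RNASEH1 had a log2 fold change of -0.04 (adjusted p = 0.67).

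Of the 26 lists, 10 were called with gap-P13, 7 higher and 3 lower. Cholesterol synthesis genes fell in 18 of 19 measured members with 0 risen (median log2 fold change -0.32, adjusted p = 2.97e-06). Besides LSS, MVD, an enzyme of the mevalonate pathway, fell by 0.81, the sterol carrier STARD4 by 0.65 and the thiolase ACAT2 by 0.53. Fatty acid synthesis genes fell in 12 of 16 with 1 risen (median -0.47, adjusted p = 0.000206). LPIN1, which encodes a phosphatidate phosphatase, fell by 2.76, the acyl-CoA synthetase ACSL1 by 1.56 and the acetyl-CoA synthetase ACSS2 by 1.23. Hepatocyte transcription factors fell in 10 of 14 with 0 risen (median -0.43, adjusted p = 0.00189), among them the nuclear receptor gene RXRA, from 1672 to 590.2, PROX1, which fell by 0.80, and GATA4, which fell by 0.58. NF-kappaB and inflammatory genes rose in 16 of 19 (median 0.998, adjusted p = 2.52e-06). The chemokines CXCL2 and CXCL5 rose by 2.30 and 2.14, and NFKBIZ by 1.43. The 1 member that fell was NFKB1, by 0.96, named after its value was seen. Immediate early genes rose in 18 of 19 with 0 fallen (median 0.69, adjusted p = 2.44e-06), with EGR1 at 1.04, ATF3 at 0.81 and JUN at 0.69. Targets of p53 rose in 15 of 21 and fell in 3 (median 0.43, adjusted p = 0.00428), with the DNA repair gene DDB2 at 2.08, GADD45A at 0.74 and TP53I3 at 0.74. Genes of the integrated stress response rose in 13 of 22 and fell in 4 (median 0.38, adjusted p = 0.00743), with the amino acid transporter subunit SLC3A2 at 1.23, DDIT4 at 1.22 and asparagine synthetase ASNS at 0.65. On the hybridization spikes 12 p53 targets rose and 4 fell (median 0.29), and 11 stress response genes rose and 4 fell (median 0.24).

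The other 3 lists called with gap-P13 had smaller medians. Cell cycle genes rose in 20 of 34 and fell in 4 (median 0.20, adjusted p = 0.0105). Cyclin B1 (CCNB1) rose by 0.68 and the mitotic kinase AURKA by 0.74, while the replication licensing factor MCM3 fell by 0.48. On the hybridization spikes 10 rose and 5 fell, with a median of 0.06. The call ended once the median of each gene's length decile was taken off (adjusted p = 0.0913). Targets of NRF2 rose in 10 of 20 and fell in 2 (median 0.27, adjusted p = 0.0108, adjusted p = 0.0869 with an estimated correlation). Heme oxygenase HMOX1 rose by 1.48 and OSGIN1 by 1.19, while PGD, an enzyme of the pentose phosphate pathway, fell by 1.58. Quantile normalization ended the NRF2 call (adjusted p = 0.182), with 10 risen and 5 fallen at a median of 0.12, and on the spikes the median was 0.13. Ribosomal protein genes rose in 16 of 20 with 0 fallen (median 0.25, adjusted p = 0.00424, adjusted p = 0.692 with an estimated correlation), with RPL19 at 0.31. On the spikes 10 of them rose and 2 fell, with a median of 0.11. After quantile normalization 2 rose and 2 fell (adjusted p = 0.782), and taking off the length decile gave an adjusted p of 0.427. The 99th percentile of signal, which reflects the most abundant transcripts, was 111.6% of control on the gap-P13 arrays (exact permutation p = 0.0286, the smallest that 4 against 4 can give, and 0.103 after Benjamini-Hochberg adjustment over the array measures). A link to the ribosomal protein list was not tested. Adjusted over the list alone, the risen members were 18 among ribosomal proteins, 21 among cell cycle genes and 14 in the integrated stress response, and the other 7 called lists kept the counts given. In all 10 lists the members' mean, relative to that of all genes, moved in the called direction on all 4 treated arrays. Most lists without a call also moved 1 way on all 4 arrays, so this does not set called lists apart. No called median changed sign under quantile normalization, median centring or scaling on the hybridization spikes. Scaling on the poly-A spikes was not tried. They read 122.7% of control on the gap-P13 arrays, against 109.8% for the hybridization spikes. Median centring left 13 cholesterol synthesis genes fallen and 1 risen (median -0.21).

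Lists without a call also held genes that moved. Interferon-stimulated genes rose in 10 of 23 with gap-P13 and fell in 0, which missed the threshold (median 0.43, adjusted p = 0.0654), and in 2 with gap-A13 (adjusted p = 0.0985). ISG15, an interferon-induced modifier, rose by 0.59 with gap-P13 and 0.24 with gap-A13. For most other lists without a call, the balance with gap-P13 depended on the scaling. Heat shock genes rose in 8 of 13 and fell in 3 as deposited, but rose in 2 and fell in 4 on the hybridization spikes. Autophagy and lysosome genes rose in 13 of 20 and fell in 5, and 6 each way on the spikes, and hypoxia and glycolysis genes rose in 10 of 23 and fell in 4, and 5 each way on the spikes. RNase H and RNA decay enzymes rose in 10 of 22 and fell in 10, against 5 and 11 on the spikes, with EXOSC10 and XRN1, both RNA exonucleases, down by 0.88 and 1.01. Phosphorothioate-binding and paraspeckle proteins rose in 9 of 18 and fell in 2, and 4 each way on the spikes. Endoplasmic reticulum chaperones rose in 6 of 19 and fell in 7, against 3 and 9 after quantile normalization and 1 and 11 on the spikes. Once the median of each gene's length decile was taken off, camera called them lower with gap-P13 (adjusted p = 0.0155) and with gap-A13 (adjusted p = 0.00348). Fatty acid oxidation and ketogenesis genes rose in 3 of 17 and fell in 6, against 3 and 8 on the spikes. Hepatocyte secreted proteins rose in 11 of 30 and fell in 4 with a median of 0.18, but rose in 9 and fell in 8 after quantile normalization, where the median turned to -0.02, and rose in 4 and fell in 8 on the spikes. Apolipoproteins and lipoprotein handling genes rose in 7 of 17 and fell in 5, against 2 and 5 on the spikes, and extracellular matrix and TGF-beta genes rose in 5 of 19 and fell in 5, against 3 and 7. Drug-metabolising enzymes and transporters rose in 4 of 16 and fell in 4, with the efflux pump ABCB1 up by 1.07 and CYP1A1, a cytochrome P450 gene, down by 1.68. Markers of other cell types showed no call. With gap-P13, fibroblast markers rose in 0 of 7 and fell in 1, leukocyte markers rose in 2 of 7 and fell in 0, biliary markers rose in 2 of 7 and fell in 3, and the 1 measured endothelial marker did not pass. In 13 of the 78 list results the median, the mean and camera differed in sign, and none of these was called.

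**Figure D2:**
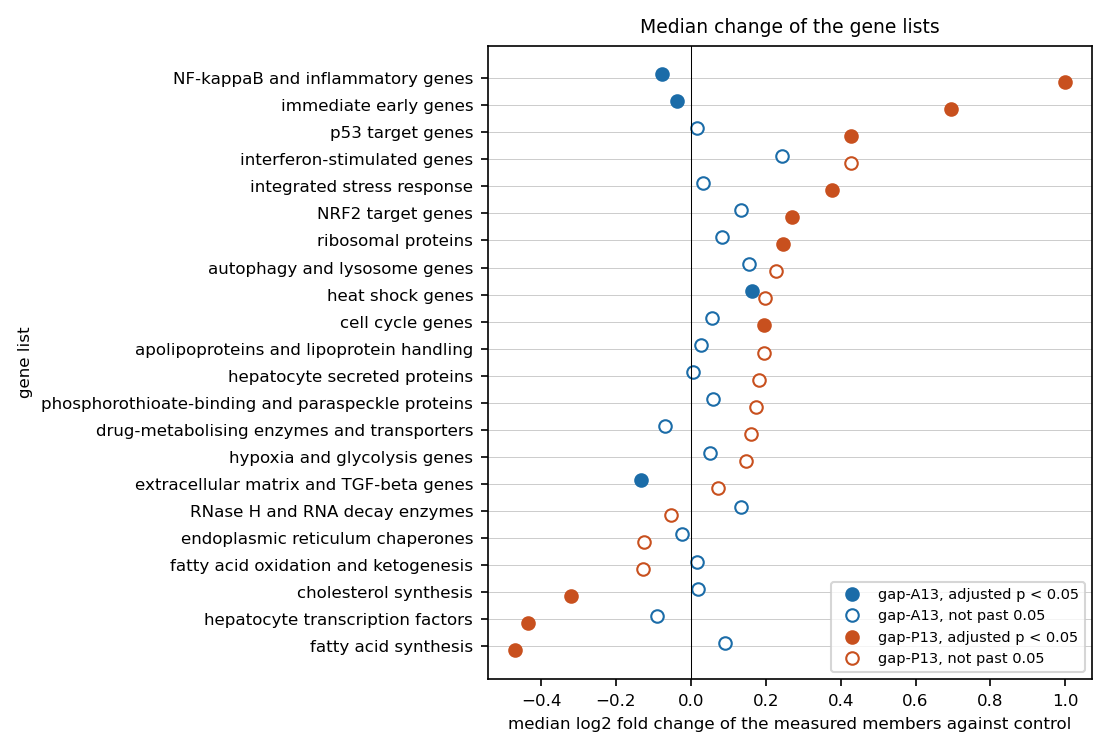
Median log2 fold change against control of the measured members of 22 gene lists, for gap-A13 and gap-P13 (4 arrays each against 4 controls). Filled points passed an adjusted p of 0.05 in camera, and the medians ran from -0.47 for fatty acid synthesis to 0.998 for NF-kappaB and inflammatory genes, both with gap-P13.

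Of the control genes, GAPDH had a log2 fold change of 0.10 with gap-A13 (adjusted p = 0.328) and 0.23 with gap-P13 (adjusted p = 0.00535). The gap-P13 value was 0.01 after quantile normalization, 0.34 after median centring and 0.10 after scaling on the hybridization spikes (adjusted p = 0.126). ACTB with gap-P13 was 0.12 (adjusted p = 0.313), and its sign turned to -0.11 after quantile normalization (adjusted p = 0.0129) and to -0.02 on the spikes (adjusted p = 0.864), while median centring gave a called rise of 0.22 (adjusted p = 0.0385). Spike-in RNA that is added equally to all arrays read 109.8% of control on the gap-P13 arrays for the hybridization spikes and 122.7% for the poly-A spikes (exact permutation p = 0.0286 each, 0.103 adjusted). The median log2 fold change of all genes with gap-P13 was 0.06 as deposited, 0.16 after median centring and -0.08 after scaling on the hybridization spikes, so directions of small changes are relative to it. The share of called genes that were higher was 54.9% as deposited, 65.7% after median centring and 37.2% after scaling on the spikes.

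The 2 oligonucleotides were compared directly at the same concentration and time. APOB was lower with gap-A13 than with gap-P13 by a log2 difference of -1.66 ± 0.05 (SE, n = 4 each, 95% interval -1.77 to -1.56), and RNASEH1 by -0.55 ± 0.05. FNBP1L (-3.54), KMT2E (-3.24) and INHBA (-2.90), which encodes an activin subunit, were among the 5 genes furthest below their gap-P13 level, and MIR181A2HG (-3.09) had 2 gap-A13 arrays at the floor. SNX19 (3.47), MSI2 (3.41), TEX15 (3.20), VAC14 (3.09) and MDC1 (3.01), a DNA damage checkpoint gene, were furthest above it, with 3 gap-P13 arrays of SNX19 and 2 of VAC14 at the floor. Other probe sets gave smaller differences for some of these genes, 0.75 and 3.01 for SNX19, 0.86 for VAC14, -2.84 and -0.61 for INHBA, and -0.50 and -0.09 for RNASEH1, the last not called (adjusted p = 0.558). The 8 others of MSI2 ran from -0.29 to 3.14, 1 of them called in the opposite direction. By limma, 6578 of 14078 genes differed, 3218 higher and 3360 lower with gap-A13, and 748 higher and 410 lower by at least 2-fold (1001 and 285 on the hybridization spikes, 648 and 341 with a pseudocount). APOB had an adjusted p of 4.1e-13 and FNBP1L 4.01e-15. The groups did not overlap for 6013 genes (42.7%, chance 2.86%), which include every gene named in this comparison. The median of all genes was -0.02 as deposited, -0.10 after median centring and 0.13 on the spikes, and the share of called genes higher with gap-A13 was 48.9%, 37.9% and 68.9%. A further 7500 genes did not pass the test, and for 5575 of them (74.3%) the 95% interval of the difference lay within 2-fold.

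In the same direct comparison 9 lists were called. NF-kappaB and inflammatory genes were lower with gap-A13 in 16 of 19 members and higher in 0 (median -0.997, adjusted p = 2.82e-08), and immediate early genes in 17 of 19 and 0 (median -0.80, adjusted p = 2.82e-08). CXCL2 differed by -2.60, CXCL8 by -2.35 and CCN1 by -1.12. Cholesterol synthesis genes were higher with gap-A13 in 18 of 19 and lower in 0 (median 0.43, adjusted p = 3.62e-07), and fatty acid synthesis genes higher in 12 of 16 and lower in 1 (median 0.50, adjusted p = 0.000129), with LPIN1 at 3446 against 432.2 and LSS at a log2 difference of 1.75. The integrated stress response was lower in 12 of 22 and higher in 4 (median -0.36, adjusted p = 0.00525), with SLC7A11, a cystine transporter, at -1.42. Targets of p53 were lower in 14 of 21 and higher in 2 (median -0.38, adjusted p = 0.00525, adjusted p = 0.0505 with an estimated correlation), with DDB2 at -2.22. On the hybridization spikes 11 p53 targets were lower and 5 higher (median -0.23), and 11 stress response genes lower and 4 higher (median -0.22). Hepatocyte transcription factors were higher in 6 of 14 and lower in 1 (median 0.39, adjusted p = 0.0484, adjusted p = 0.111 with an estimated correlation). Cell cycle genes were lower in 18 of 34 and higher in 5 (median -0.15, adjusted p = 0.0414, adjusted p = 0.0798 with an estimated correlation), and ribosomal proteins lower in 11 of 20 and higher in 1 (median -0.17, adjusted p = 0.0304, adjusted p = 0.729 with an estimated correlation). Adjusted over the list alone, 18 immediate early genes, 13 integrated stress response genes and 13 ribosomal proteins were lower, 19 cholesterol and 14 fatty acid synthesis genes were higher, and the other 4 lists kept their counts.

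Single arrays decided 3 of these 9 list calls. Hepatocyte transcription factors lost theirs without control replicate 1 (adjusted p = 0.0507), without gap-A13 replicates 1 and 3 (0.0513 and 0.0589) and without gap-P13 replicates 1, 2 and 3 (0.0669, 0.0538 and 0.0575). Cell cycle genes lost theirs without gap-A13 replicate 2 (adjusted p = 0.0508) or gap-P13 replicate 2 (0.0538), and ribosomal proteins without gap-A13 replicates 1 and 3 (0.0674 and 0.0756) or gap-P13 replicates 1 and 2 (0.115 and 0.0508). Quantile normalization ended all 3 as well (0.0588, 0.0942 and 0.741). Scaling on the hybridization spikes ended those of cell cycle genes (0.172, with 10 lower and 7 higher at a median of -0.003) and ribosomal proteins (0.29, with 1 lower and 2 higher at a median of -0.02), as did taking off the length decile (0.1 and 0.427), and dropping the signal floor ended that of the transcription factors (0.0524). Of the 23 list calls in the 3 comparisons, 15 held with an estimated correlation, namely 2 of 4 with gap-A13 (matrix and heat shock genes), 8 of 10 with gap-P13 (all but NRF2 targets and ribosomal proteins) and 5 of 9 between the oligonucleotides. Many of these held narrowly, at an adjusted p of 0.0474 by camera. With gap-A13 this was so for both lists. With gap-P13 it was so for p53 targets, the integrated stress response, cholesterol synthesis and cell cycle genes. Between the oligonucleotides it was so for the integrated stress response and cholesterol synthesis. The tests of fry ask whether the genes of a list move on balance 1 way, without reference to other genes, and called 14, 23 and 22 lists.

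Genes moved by both oligonucleotides included OLA1, an ATPase of the Obg family, which fell from 11151 ± 679 in control to 2012 ± 116 with gap-A13 and 1730 ± 204.5 with gap-P13 (SD, n = 4). PTPRG had log2 fold changes of -3.16 and -3.24, and RGCC rose by 1.54 and 1.76. The genes called in both comparisons in the same direction numbered 1594, 894 higher and 700 lower, and 391 were called in opposite directions. Independent lists of these sizes would share 386.8 and 277.7. Both comparisons use the same 4 control arrays, which alone gave a covariance of 0.0267 in 100 simulated pairs of unchanged groups, against an observed covariance of 0.0907. These pairs had 0 shared calls, but unchanged groups yield almost no calls at all. That count therefore cannot show how far shared controls swell the overlap among changed genes. With the controls split 2 and 2 between the oligonucleotides, and so fewer arrays, 887 to 1042 genes were shared. The number that independent lists would share was not computed for these splits. At least 2-fold lower with both were 93 genes, where 14.1 would be expected of independent lists, and 27 were at least 2-fold higher with both. Of the 219 genes that gap-A13 lowered at least 2-fold, gap-P13 lowered 150 and raised 22, and 47 were not called with it. The log2 fold changes of all genes correlated with r = 0.395 across genes, below the mean of 0.5 that shared controls gave in the simulated groups, where noise alone was present.

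Shared falls were compared in size. PTPRG differed by 0.08 between gap-A13 and gap-P13 (95% interval -0.48 to 0.63, adjusted p = 0.846) and LOC103344931 by -0.08 (-0.83 to 0.66, adjusted p = 0.873). IMMP2L differed by 0.57 (-0.20 to 1.33, adjusted p = 0.219), an interval that reaches beyond 2-fold. OLA1 fell further with gap-P13 by 0.22 ± 0.08 (SE, adjusted p = 0.0226), a call that ended without gap-A13 replicate 1 or 3 (adjusted p = 0.0569 and 0.0607) or gap-P13 replicate 1 (adjusted p = 0.0729), and SOX6 further with gap-A13 by a difference of -0.72 ± 0.13 (SE, adjusted p = 0.000179). Of the shared rises, RGCC differed by -0.23 (-0.52 to 0.07, adjusted p = 0.199), DNAJC12 by -0.01 (-0.72 to 0.70), TCP10L by 0.21 (-0.44 to 0.86) and AQP10, which rose by 1.52 and 1.67 with values that overlapped those of control, by -0.15 (-1.09 to 0.79, adjusted p = 0.82). ZGLP1 rose by 1.31 and 2.35, further with gap-P13 (difference -1.04, -1.90 to -0.18, adjusted p = 0.0465), a call that ended without gap-A13 replicate 1 (adjusted p = 0.148) or 4 (0.0776) or gap-P13 replicate 1 (0.105), 2 (0.121) or 3 (0.0566). Its rise with gap-A13, where values overlapped those of control, was no longer called without control replicate 2, 3 or 4 (adjusted p = 0.0857, 0.0946 and 0.0842) or gap-A13 replicate 2, 3 or 4 (0.0956, 0.0829 and 0.0699). That of AQP10 was not called without control replicate 1, 2 or 4 (0.0657, 0.0654 and 0.0728) or gap-A13 replicate 2 (0.0703). Of the 1594 genes shared in direction, 879 differed between the oligonucleotides by the direct test, and for 690 the test was not passed and the interval lay within 2-fold. The 391 genes called in opposite directions include CXCL8 (-0.94 with gap-A13, 1.41 with gap-P13), SLC7A11 (-0.82 and 0.60) and FNBP1L (-3.17 and 0.37).

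**Figure D3:**
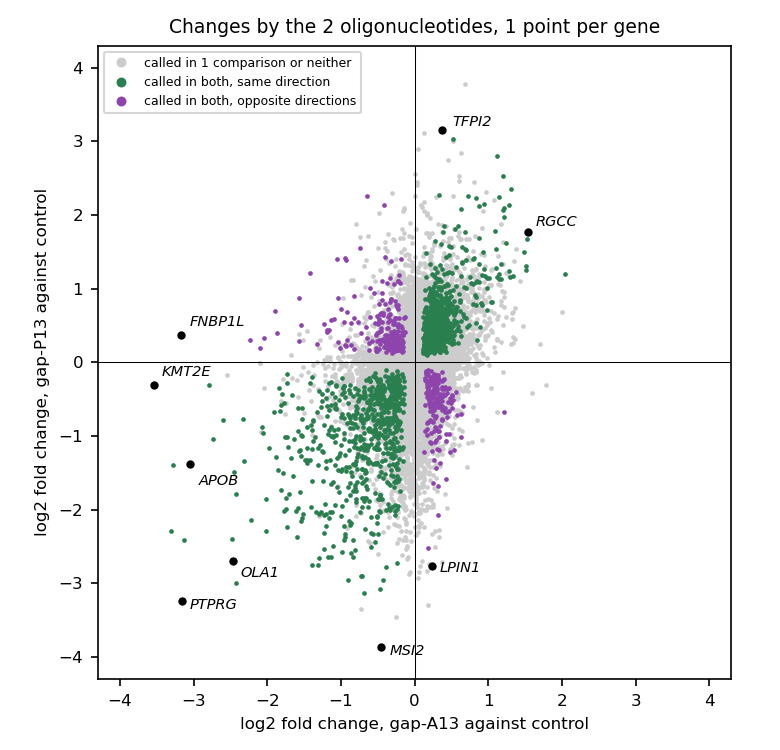
Log2 fold change against control of 14078 genes, gap-A13 on the horizontal and gap-P13 on the vertical axis, 1 point per gene. Green points (1594) were called in both comparisons in the same direction and purple points (391) in opposite directions, and named genes are marked in black.

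Long genes fell more than short ones with both oligonucleotides. In the 10% of genes with the longest gene bodies (1407 genes, median 245 kb), the median log2 fold change was -0.17 with gap-A13 and -0.52 with gap-P13, against 0.06 and 0.09 in the other genes. Among them 30.6% were called lower with gap-A13 and 56.6% with gap-P13, compared with 2.56% and 7.46% of the shortest 10%. KMT2E spans 101 kb, PTPRG 736 kb, GPHN 1230 kb, MSI2 446 kb and SHANK2 785 kb, and APOB 42.6 kb, where the median of all tested genes was 28.2 kb. Genes at least 2-fold lower had a median length of 183 kb with gap-A13, 137 kb with gap-P13 and 433 kb when lower with both. Per treated array, the rank correlation of change with length across 14064 genes was -0.188 ± 0.018 with gap-A13 and -0.297 ± 0.029 with gap-P13 (SD, n = 4). Each control array against the other 3 gave -0.059 to 0.057. By camera, the longest 10% of genes were lower than the others with gap-A13 and with gap-P13 (adjusted p = 8.46e-21 and 1.01e-22, each 3.24e-07 with an estimated correlation).

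**Figure D4:**
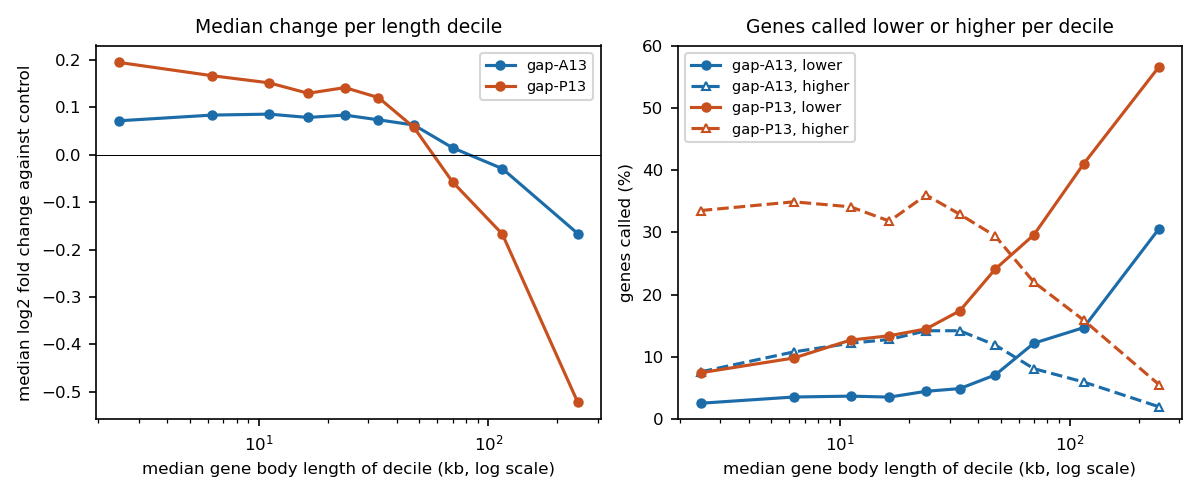
Genes in 10 groups of equal size by gene body length (median length in kb, log scale), with the median log2 fold change against control on the left and the percent of genes called lower or higher on the right. With gap-P13, the share called lower ran from 7.46% in the shortest group to 56.6% in the longest, and with gap-A13 from 2.56% to 30.6%.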

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

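The tests of gap-A13 material at 1 share for all genes and of a general fall of liver secretory transcripts, those of the shared loss for each oligonucleotide and of APOB against genes of its length, and those on the hybridization spikes, were chosen only after the results were seen. Chance was tested for each count of called genes by regrouping the 8 arrays of a comparison in all 35 ways. In each comparison 1 split, the real one, gave as many genes. The real counts were 2629 with gap-A13, 7070 with gap-P13 and 6578 between them, and the highest count of another split was 0, 1 and 1. With 35 splits, the smallest p that this regrouping can give is 0.0286. The other splits also mix groups that differ, which widens the spread within them and lowers their counts. The test therefore cannot exclude chance.

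The oligonucleotides moved some genes apart. The direct test separated all of the 391 genes called in opposite directions against control, which follows from how they were picked and adds no evidence. The lists of NF-kappaB and inflammatory genes and of immediate early genes stood out because they were called lower with gap-A13 and higher with gap-P13. An estimated correlation ended the gap-A13 calls (adjusted p = 0.113 and 0.1), not those with gap-P13. The direct list tests by camera gave an adjusted p of 2.82e-08 for NF-kappaB and 2.82e-08 for immediate early genes. A direct difference follows from how these lists were picked and is no evidence of a fall with gap-A13. Their medians were -0.08 and -0.04 with gap-A13, against 0.998 and 0.69 with gap-P13. CXCL8 was 2685 with gap-A13, 5165 in control and 13761 with gap-P13.

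Long genes fell more with both oligonucleotides. Signal level does not account for the trend, since the partial rank correlation with length at fixed mean signal was -0.188 ± 0.018 with gap-A13 and -0.297 ± 0.029 with gap-P13 (SD over 4 arrays). Nor does scaling, since quantile normalization left -0.176 ± 0.017 and -0.283 ± 0.024. A loss of the same long transcripts by both oligonucleotides was tested among the longest 1407 genes, where the covariance less the part due to shared controls was 0.365 ± 0.023 of the mean variance. The variances were unequal (0.289 with gap-A13, 0.64 with gap-P13), which that mean hides. The common part was 0.265 ± 0.019 of the gap-P13 variance and 0.588 ± 0.039 (bootstrap SD over genes) of the gap-A13 variance. These ratios are shares only if the common loss had the same size with both oligonucleotides. Such a loss is argued against as the source of most of the gap-P13 variation and stays open for gap-A13. The medians of these genes were -0.17 and -0.52, and their changes correlated with r = 0.453, shared controls included. A common loss of unlike size is not decided by the ratios. A uniform fall of all long genes is not tested by a covariance and stays open, as does cutting at sites that are more numerous in long pre-mRNA, which may differ between sequences.

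Cholesterol and fatty acid synthesis genes fell with gap-P13. With the median of each gene's length decile taken off, the 35 measured members had a median log2 fold change of -0.43 (-0.428 ± 0.079, bootstrap SD over genes). This value argues against gene length as the whole cause. The bootstrap drew genes as if they were independent, so its SD does not measure the spread between samples. Scaling was tested in the same way and left -0.415 ± 0.075 after quantile normalization and -0.565 ± 0.097 on the hybridization spikes. A regulated fall of lipid synthesis stays open, as a hypothesis drawn from the same data that was not itself tested.

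APOB fell with gap-P13 as well as with gap-A13. If gap-A13 material had reached the gap-P13 samples, the other genes that gap-A13 lowered would fall too, and the median fold change of the 218 other genes lowered at least 2-fold was -0.79 with gap-P13 against -1.37 with gap-A13, a ratio of 0.577 ± 0.073 (APOB 0.453), as that explanation needs. With 1 share for all genes, hardly any gene lowered at least 4-fold should have a gap-P13 log2 fold change well above 0.3 times its gap-A13 value. Of 29 such genes other than APOB, 9 (31%) lay above that cutoff by over 2 standard errors, FNBP1L and KMT2E among them. These values argue against 1 share for all genes. A general fall of liver secretory transcripts is argued against by the hepatocyte secreted protein list, whose median was 0.182 ± 0.047 as deposited, -0.02 after quantile normalization and 0.05 on the hybridization spikes, far from the fall of APOB in each. Gene length is argued against for APOB by the 1407 genes of similar length around it, whose median with gap-P13 was 0.058 ± 0.013. Errors in these tests on APOB are bootstrap SDs over genes, not over samples. Effects of gap-P13 on APOB itself stay open, as do losses common to both oligonucleotides among the 218 other genes, which may explain their ratio.

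In 19 of 324 groups of 4 values, tested for 108 genes, 1 array lay far from the other 3 by Dixon's ratio of gap to range, and chance gives about 1 in 20. In the controls the ratio was 0.946 for GTF2IP20, whose replicate 2 lay above the 32.3 to 34.8 of the others, 0.89 for LTBP1, 0.911 for SLAMF7, 0.913 for SNX19 (162 in replicate 3, 254 to 265 in the others), 0.941 for TP53I3, 0.877 for UBASH3B, 0.866 for ZGLP1 (81.8 in replicate 1, 21 to 25.1 in the others) and 0.857 for AQP10 (81.8 in replicate 3, 19.3 to 23.7 in the others), and it was 1 for MIR181A2HG, PRODHLP and SUCLA2-AS1, where 3 controls were at the floor. With gap-A13 it was 0.852 for CCN2, 0.836 for MVD and 0.904 for TFPI2. With gap-P13 it was 0.849 for CXCL8 (11800 in replicate 1, 14200 to 14700 in the others), 0.923 for MCU, 0.876 for PSMD6, 0.893 for RGCC and 1 for SNX19, where 3 arrays were at the floor. Of 33 groups of array measures, 1 stood out, the poly-A spikes of gap-A13 replicate 3 at 363.3 against 387.5 to 391.1 (ratio 0.871).

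Probe sets without 1 gene symbol, which the gene tests left out, also changed. Of 5866 tested, 463 were called with gap-A13, 1900 with gap-P13 and 1715 between the oligonucleotides, or 7.89%, 32.4% and 29.2%. Among 26902 probe sets with a gene the shares were 14.0%, 44.9% and 41.9%. At least 2-fold changes numbered 15 higher and 44 lower with gap-A13, and 230 higher and 229 lower with gap-P13.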

How the results depend on the processing

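Scaling on the hybridization spikes, length-corrected list tests, and leaving out arrays for the lists, the length correlation, the shared genes and their direct comparison were tests chosen only after the data were seen. Of 95 values of the main results under other settings, 83 stayed within 1.5 times the count or 1 SD and 12 moved. Testing all 32768 probe sets singly gave 4239, 13985 and 12991 calls with gap-A13, with gap-P13 and between them, since more features were tested. Without the filter on dim probe sets the correlation with gene length was -0.14 with gap-A13 and -0.228 with gap-P13. The cause was not tested. An estimated correlation left 2 lists with gap-A13 and 5 between the oligonucleotides. The tests of fry called 14, 23 and 22, by construction without comparing with other genes. Splitting the controls gave 887 to 1042 shared genes, with fewer arrays.

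Leaving out 1 array at a time gave 2067 to 2858 calls with gap-A13, 6620 to 7068 with gap-P13 and 6119 to 6563 between them, and 248 to 265, 1306 to 1372 and 1120 to 1179 genes at least 2-fold changed. The length correlation ran from -0.216 to -0.195 and from -0.328 to -0.303, shared genes from 1234 to 1640, and lists from 3 to 5, 10 to 11 and 6 to 10. Of the named genes, 4299 values under these fits kept their call, 103 lost it and 14 gained one.

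Some single genes changed sign. Quantile normalization turned ACTB to -0.109 with gap-P13 and 0.118 in the direct comparison, and spike scaling turned LYZ to 0.011 there. The mean of a gene's probe sets, which adds weaker probe sets, turned GDF15 to -0.202 and PSPC1 to 0.004 with gap-A13, XRCC5 to 0.003 with gap-P13, and CHORDC1 to -0.061 and HNRNPU to 0.161 in the direct comparison. The cause was not tested. Of the other named-gene values, quantile normalization kept 352, spike scaling 349, the probe set mean 333 and no floor 363. List calls kept were 17 of 23, 21, 22 and 22 under quantile normalization, spike scaling, no floor and fry, and 19 with length taken off. Taking length off also added camera calls. These were endoplasmic reticulum chaperones, lower with both oligonucleotides, and NRF2 targets, lower with gap-A13 than with gap-P13 (adjusted p = 0.0415).

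With replicate number as a replicate block, 2635, 7154 and 6589 genes were called. Of 12 arrays, 3 correlated best with arrays of their own number. Correlations ran from -0.058 to 0.084 for the same number and from -0.108 to 0.131 for different numbers. No pairing by number was detected, though this cannot show whether the samples were paired in the design. Signals near the floor of 18.6 limit fold changes from dim genes, for which the size is set by the floor.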

Other observations

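Gene families were also examined by symbol, and lncRNA genes by their annotation, all tests of them chosen only after the results were seen. Some families hold members of the fixed lists, as chemokines do with CXCL8 and dual-specificity phosphatases with DUSP1. Their results partly count the same genes again. With gap-A13, mitochondrial ribosomal proteins were higher, with 27 of 76 measured members risen and 2 fallen (median log2 fold change 0.13, adjusted p = 3.89e-07, adjusted p = 0.179 with an estimated correlation), MRPL46 at 0.51 ± 0.04 (SE, n = 4). With the median of each gene's length decile taken off, the median was 0.06. MRPS11 went the other way and fell by 2.55 ± 0.12. Proteasome subunits were higher in 23 of 45 and lower in 2 (median 0.16, adjusted p = 0.000129, adjusted p = 0.179 with an estimated correlation). The length-corrected median was 0.08. PSMD6 rose by 0.39, while PSMD14, a deubiquitinating subunit, fell by 1.01. Cytosolic aminoacyl-tRNA synthetases, which charge tRNA with amino acids, rose in 5 of 14 and fell in 0 (median 0.16, adjusted p = 0.0015, adjusted p = 0.254 with an estimated correlation), with a length-corrected median of 0.08. Chemokines fell in 3 of 14 with gap-A13 and rose in 0 (adjusted p = 0.0215, adjusted p = 0.16 with an estimated correlation).

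With gap-P13, chemokines rose in 7 of 14 and fell in 1 (median 0.79, adjusted p = 0.0269, adjusted p = 0.16 with an estimated correlation). Collagens fell in 10 of 22 and rose in 0 (median -0.25, adjusted p = 0.0269, adjusted p = 0.16 with an estimated correlation), with COL27A1 down by 1.36 and COL4A5 by 0.77. Collagen genes are long, with a median of 139 kb, and their length-corrected median was -0.16. Zinc finger genes of the ZNF series rose in 150 of 425 and fell in 47 (median 0.20, adjusted p = 0.0455, adjusted p = 0.19 with an estimated correlation), and on the hybridization spikes in 92 and 62, with a median of 0.07, while the length-corrected median was 0.10. Mitochondrial ribosomal proteins rose in 42 of 76 and fell in 9 (median 0.16, adjusted p = 0.0243, adjusted p = 0.469 with an estimated correlation), and moved in 16 each way on the spikes (median 0.03), while the length-corrected median was 0.02. In the direct comparison, replication-dependent histones were lower with gap-A13 in 11 of 35 and higher in 1 (median -0.33, adjusted p = 0.0269, adjusted p = 0.16 with an estimated correlation), and dual-specificity phosphatases lower in 12 of 20 and higher in 2 (median -0.34, adjusted p = 0.0455, adjusted p = 0.162 with an estimated correlation). The length-corrected medians were -0.21 and -0.26, and those on the spikes -0.19 for each, with 9 histones lower and 3 higher and 7 phosphatases lower and 2 higher. In all, 12 of 57 family tests were called, and 0 with an estimated correlation.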
